A study of Mus musculus with 32 samples.

How the data were processed

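Gene expression was measured on Illumina beadchip arrays in 32 samples of mouse small intestinal organoids, in 8 groups of 4. Organoids are epithelial structures grown from intestinal crypts in a gel. Per the labels, each sample pooled about 300 organoids, exposure lasted 3 h, and 200 ng of RNA was labelled. The labels call the samples of a group independent biological replicates and name 1 organoid line, so p-values measure the spread between cultures of that line and not between animals.

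The deposited intensity values are one summarised brightness per probe and array, not background-corrected and not normalised, exported with GenomeStudio per the submitters' processing notes. The deposited detection p-value of each probe gives its standing against the background of its array. The authors' table of processed values is on a log2 scale and quantile-normalised; its column medians were all 5.58 after rounding, and it correlated with the values computed here at r = 0.994 on every array. The versions of GenomeStudio and limma that the authors used are not given in the sources used here.

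From the intensities, background was corrected with limma's normexp model, in which the background was estimated from the detection p-values, with an offset of 16, followed by quantile normalisation and log2. A probe was kept when its detection p was under 0.05 on at least 4 arrays, which left 13462 of 25697 probes. Gene symbols came from the platform annotation and were checked against the RefSeq gene table, which changed 0 symbols. A symbol was given for 23978 probes, several symbols for 0 and none for 1719. Each gene was represented by its detected probe with the highest mean, giving 9291 genes. Of the named genes that changed, 98 gene and comparison pairs had another detected probe, whose sign was opposite in 11, 2 of them at an unadjusted p under 0.05. In 30 of the 98 no other probe changed the same way at an unadjusted p under 0.05; those printed in the report or plotted are named there. No genomic coordinates are given, since no genome build was named for the probes.

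One linear model with the 8 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3 (24 residual degrees of freedom), with moderated variances that follow the mean. Adjusted p is the Benjamini-Hochberg value over the 9291 genes of a comparison, and a gene is said to have risen, fallen or changed where it was under 0.05. There were 11 comparisons. Errors beside log2 fold changes are standard errors of the fit, with n = 4 arrays per group throughout. The number of arrays limits the precision: the median half-width of a 95% confidence interval was 0.31 on the log2 scale. A gene whose probes were above background on no array of a group has only a bound there. It is given as at least N-fold, the bright group's mean against the higher of the lowest detected signal and the probe's own value on each array of the dim group.

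The rule for the genes named was fixed before the data were examined. For the comparisons of conditioned media and acids it took up to 10 genes of highest and 10 of lowest log2 fold change among changed genes whose groups did not overlap, up to 4 changed members of each gene list, and the genes Angptl4, Ffar2, Pparg, Hdac3 and Hdac5, which are known from the study as its follow-up genes. Where fewer than 5 genes changed it took the 5 of smallest p, and for the other comparisons up to 4 genes at each end. Not every gene the rule took is printed.

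The 34 gene lists were also fixed before the data were examined. They covered the study's follow-up genes, histone deacetylases, genes responsive to their inhibitors, short-chain fatty acid receptors and metabolism, PPAR targets and fatty acid oxidation, cholesterol synthesis, lipogenesis, chylomicrons, glycolysis, gluconeogenesis, NF-kB and chemokines, interferon, antimicrobial defence, AhR targets, oxidative stress (NRF2 targets), ER stress and amino acid response, hypoxia, immediate early genes, heat shock, metallothioneins and metal transport, p53 targets, cell cycle, Wnt targets, tight junctions, bile acid and xenobiotic genes, and markers of stem, enterocyte, goblet, Paneth, enteroendocrine, tuft, immune, mesenchymal and endothelial cells. The 31 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Adjusted p for a list is over the 31 lists of a comparison. Counts "adjusted over the list alone" use the members of the list in place of all genes.

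Correlations between responses are across genes, which are not independent replicates, so their p-values are exact and two-sided over the 70 ways of assigning the 8 arrays of the bacterial comparison, with 0.0286 as the smallest possible value. For comparisons with shared control arrays, unchanged groups were simulated 100 times and the controls were also split into 2 and 2, with values given as means over the 6 splits. On simulated data for the A. muciniphila comparison with 9291 genes, 200 of them changed, 33.0% of changes of 0.5 and 89.0% of changes of 1 on the log2 scale were recovered, 5.43% of the calls were false, and 0 genes were called in the unchanged F. prausnitzii pair. Recovery depends on the share of genes changed. The real A. muciniphila comparison called 2094, so these rates do not give its recovery.

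Each of 4 slides held 2 groups, one on rows 1 to 4 and the other on rows 5 to 8. Slide 1 held acetate and butyrate, slide 2 both A. muciniphila groups, slide 3 both F. prausnitzii groups, and slide 4 propionate and control. Comparisons within a slide are therefore those of each conditioned medium with its medium, propionate with control, and butyrate with acetate. The difference between the bacterial responses is one of within-slide differences, so slide cancels in it. In the other comparisons slide and treatment cannot be told apart. Alternatives were the authors' deposited log2 values, no background correction, cyclic loess, no or a stricter detection filter (p under 0.01 on all 4 arrays of a group), array quality weights, the array row as a covariate, all probes, only the groups compared, other gene list tests, and leaving out each array in turn. F. prausnitzii medium against A. muciniphila medium, and the array position within each 4 rows as a factor, were added after seeing the data.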

Results

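The study exposed mouse small intestinal organoids for 3 h to medium conditioned by the gut bacteria Akkermansia muciniphila or Faecalibacterium prausnitzii, to the same bacterial media without growth, to 5 mM acetate, propionate or butyrate, or to culture medium alone as control. Acetate, propionate and butyrate are short-chain fatty acids that gut bacteria make, with chains of 2, 3 and 4 carbons. Each of the 8 groups held 4 arrays. Mean probe intensity per array ran from 392 to 722, and 10636 to 11782 probes were detected per array. Replicate arrays correlated at r = 0.984 to 0.991 across genes. Arrays of different groups reached 0.991 as well, so these values do not set replicates apart from other arrays. The first principal component held 37.9% of the variance. Its group means ran from -29.0 ± 1.08 (SD, n = 4) in A. muciniphila medium and -25.6 ± 2.44 in control, through -16.7 ± 1.68 in acetate, -2.74 ± 2.19 in A. muciniphila conditioned medium, 10.3 ± 1.58 in propionate, 15.1 ± 4.31 in F. prausnitzii medium and 20.2 ± 1.48 in F. prausnitzii conditioned medium, to 28.4 ± 3.99 in butyrate.

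**Figure D1:**
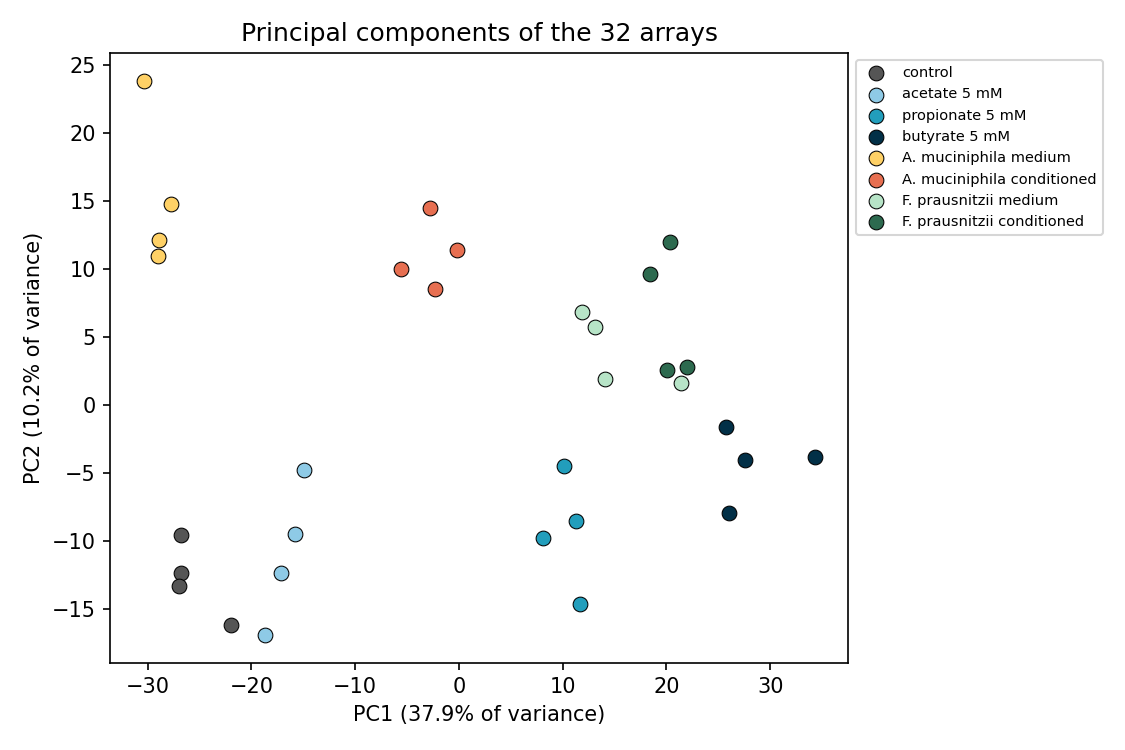
Each point is 1 of the 32 arrays, placed by its first (x axis) and second (y axis) principal component of log2 expression and coloured by group, with 4 arrays per group. Control arrays lie between -26.9 and -22.0 on the first component and butyrate arrays between 25.8 and 34.3.

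The first question was how organoids responded to medium conditioned by A. muciniphila, set against its medium without growth on the same slide. Conditioned medium lowered Hmox1, the haem-degrading enzyme and a marker of oxidative stress (log2 fold change -2.24 ± 0.25), the histone methyltransferase gene Kmt5b (-2.10 ± 0.21, another probe -1.19 ± 0.19) and Ihh, a hedgehog ligand of the epithelium (-2.06 ± 0.23). It raised Ikbip (2.58 ± 0.18), Aph1b, a subunit of gamma-secretase (2.17 ± 0.18), Rem2 (1.92 ± 0.16), Rassf4 (1.81 ± 0.18) and the beta-arrestin gene Arrb2 (1.71 ± 0.13). Another detected probe of Ikbip gave 0.25 ± 0.23. Rep15 (-2.00 ± 0.23), Pitpnm2 (-1.91 ± 0.22), Epc2 (-1.85 ± 0.14), Cc2d2a (-1.76 ± 0.19), Dis3l (-1.69 ± 0.18) and the goblet cell factor Spdef (-1.64 ± 0.22) fell. In all, 2094 of 9291 genes changed, 1110 higher and 984 lower.

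Oxidative stress genes fell as a list with A. muciniphila conditioned medium: 9 of 18 tested members fell, 0 rose and 9 did not pass, with Slc7a11 (-1.43 ± 0.28), Gclc (-0.93 ± 0.22) and Srxn1 (-0.66 ± 0.12) besides Hmox1. The list's adjusted p was 0.00147, and adjusted p = 0.0290 with an estimated correlation; 10 fell and 1 rose when adjusted over the list alone. Among cell cycle genes 11 of 29 fell and 0 rose, such as Ube2c (-0.95 ± 0.26), Rrm2 (-0.77 ± 0.18) and Pcna (-0.72 ± 0.18). Adjusted over the list alone 17 fell; the list's adjusted p was 0.000170, and adjusted p = 0.476 with an estimated correlation. Of 19 genes of PPAR targets and fatty acid oxidation 9 rose and 0 fell, among them Plin2, which coats lipid droplets (0.73 ± 0.16), Ehhadh (0.66 ± 0.16) and Acadm (0.51 ± 0.10, another probe 0.21 ± 0.20). Adjusted over the list alone 11 rose (adjusted p = 0.00303, and adjusted p = 0.50 with an estimated correlation). Of 24 NF-kB and chemokine genes 7 rose and 0 fell, including the inhibitor Tnfaip3 (0.72 ± 0.16) and Irf1 (0.68 ± 0.12). Adjusted over the list alone 9 rose and 1 fell (adjusted p = 0.0105, and adjusted p = 0.116 with an estimated correlation). Hypoxia genes fell in 6 of 21 cases, such as Ak4 (-0.69 ± 0.15) and Vegfa (-0.53 ± 0.13), with 6 adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.600 with an estimated correlation). The other 26 lists did not pass, with adjusted p from 0.0743 to 0.918. Among single members of these, the enteroendocrine factors Pax4 (-0.93 ± 0.19) and Neurog3 (-0.78 ± 0.23) and the stem cell marker Lgr5 (-0.75 ± 0.18) fell, and Egr1 rose (0.85 ± 0.14). Of lists with too few genes to test, Laptm5 (-0.78 ± 0.23) fell among 4 immune genes and Esam (-0.77 ± 0.15) among 3 endothelial genes. Against control, on another slide, the medium itself was lower for PPAR and fatty acid oxidation genes (7 of 19) and higher for oxidative stress and hypoxia genes. Cell cycle genes were lower there too, and the NF-kB list did not pass. Where the directions were opposite, a bacterial product and a lost effect of the medium cannot be told apart.

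Of the study's follow-up genes, which were chosen on these samples and are not independent evidence, the deacetylase genes Hdac5 (0.96 ± 0.14) and Hdac3 (0.39 ± 0.07) rose and Pparg (-0.82 ± 0.12, another probe -0.28 ± 0.23) and the fatty acid receptor gene Ffar2 (-0.57 ± 0.20) fell with A. muciniphila conditioned medium. Angptl4, an inhibitor of lipoprotein lipase, differed by -0.39 ± 0.19 (adjusted p = 0.154). With the array row as a covariate the count of changed genes was 1156. Conditioned medium lay on rows 1 to 4 and medium on rows 5 to 8, so that row and treatment are partly confounded.

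For F. prausnitzii the same comparison called no gene, with 85 µl of supernatant or medium added to 500 µl against 250 µl for A. muciniphila. Per the labels its medium contained 9 mM propionate and 2.5 mM acetate before mixing. That medium by itself differed from control, on another slide, in 3348 genes. Effects that medium and conditioned medium share cancel here, so the count does not measure the whole effect of the supernatant. The genes of smallest p, none of which passed in limma, were Cdx2, the intestinal identity factor (-0.54 ± 0.12, adjusted p = 0.311), P2ry6 (-0.84 ± 0.18), Grhl2 (-0.57 ± 0.14), Hivep1 (-0.85 ± 0.21) and Bsdc1 (0.45 ± 0.11). With the array position within each 4 rows as a factor, an alternative added after seeing the data, P2ry6 passed (adjusted p = 0.0322). Angptl4 was not above background in the medium, so no difference is given. The other follow-up genes differed by 0.13 ± 0.20 for Ffar2, 0.10 ± 0.12 for Pparg, 0.05 ± 0.07 for Hdac3 and 0.01 ± 0.14 for Hdac5. In limma 0 of 9291 genes changed and 605 had an unadjusted p under 0.05. Leaving out F. prausnitzii medium replicate 1 gave 19. Interferon genes were the only list past the threshold of the 31 (adjusted p = 8.21e-05), with 0 of 19 members changed over all genes or adjusted over the list alone, and adjusted p = 0.974 with an estimated correlation. The interferon score per array ran from -0.26 to 1.02 in conditioned medium and from -0.61 to 0.52 in medium.

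**Figure D2:**
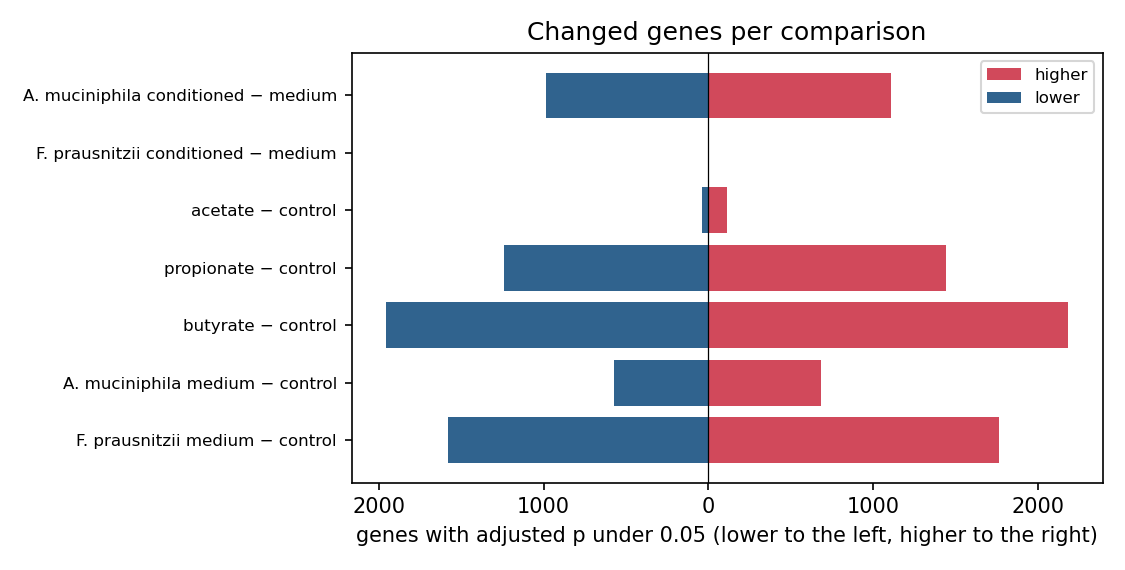
Bars give the number of genes with an adjusted p under 0.05 in limma, lower to the left and higher to the right of 0, for 7 comparisons of 4 arrays with 4. Butyrate changed 4146 genes, propionate 2687, acetate 151 and F. prausnitzii conditioned medium 0.

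The responses of both bacteria were also set against each other. Per the labels, 250 µl of supernatant or medium was added to 500 µl for A. muciniphila, but 85 µl for F. prausnitzii. The bacterial media differed too, with 5 mM glucose for A. muciniphila and 25 mM for F. prausnitzii. The labels also give 9 mM propionate and 2.5 mM acetate for F. prausnitzii medium, and neither acid for A. muciniphila medium. Set against A. muciniphila medium, on another slide, F. prausnitzii medium without growth differed in 3384 genes, with Ikbip at 3.17 ± 0.18 and Ihh at -3.45 ± 0.23. Volume, medium and bacterium cannot be told apart in this comparison. The A. muciniphila response exceeded that of F. prausnitzii by 2.54 ± 0.26 for Ikbip, 2.25 ± 0.23 for Rem2 and 2.23 ± 0.26 for Aph1b, and was lower by -2.59 ± 0.35 for Hmox1, -2.16 ± 0.32 for Ihh and -1.98 ± 0.29 for Kmt5b. The difference passed for 881 genes, 537 higher and 344 lower. It passed for oxidative stress genes, 7 of 18 of which were lower (8 adjusted over the list alone; adjusted p = 0.000292, and adjusted p = 0.0116 with an estimated correlation). Also past the threshold were PPAR targets and fatty acid oxidation, with 6 of 19 higher (8 adjusted over the list alone), NF-kB genes, with 3 of 24 higher (4), cell cycle genes, with 3 of 29 lower (3), and interferon genes, with 0 of 19 changed (0). With an estimated correlation their adjusted p was 0.858, 0.176, 0.544 and 0.858.

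Butyrate gave the most changed genes of the acids. The cysteine-rich protein gene Crip2 rose by 3.75 ± 0.17, Rgs9bp by 2.98 ± 0.18 (another probe 0.95 ± 0.22), the linker histone gene H1f2 by 2.86 ± 0.15, Anxa6 by 2.84 ± 0.20 and the actin regulators Limk1 and Wasf1 by 2.79 ± 0.22 and 2.63 ± 0.16. Neurog3, the factor that starts enteroendocrine differentiation, fell by 4.33 ± 0.23 on the log2 scale, and so did Ihh (-3.53 ± 0.23), the polycomb gene Scmh1 (-3.13 ± 0.20), the metalloprotease gene Mmp14 (-3.06 ± 0.18) and the potassium channel gene Kcnn4 (-2.91 ± 0.17). Pax4 was at least 4.38-fold lower, since it was not above background on any butyrate array. In all 4146 genes changed, 2187 higher and 1959 lower. Butyrate and control lay on different slides; against acetate, on the slide of butyrate, 3605 genes changed, with Neurog3 at -4.13 ± 0.23 and Crip2 at 3.44 ± 0.17.

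Cell cycle genes fell with butyrate: 23 of 29 fell, 1 rose and 5 did not pass, with Ccnd1 (cyclin D1, -1.79 ± 0.14), Tk1 (-1.47 ± 0.11) and Aurka (-0.98 ± 0.15). Adjusted over the list alone 25 fell and 1 rose, and adjusted p was 0.253 with an estimated correlation. Stem cell markers fell in 8 of 13 cases, among them Lgr5 (-2.27 ± 0.18) and Olfm4 (-1.01 ± 0.22), with 8 adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). Tight junction genes fell in 9 of 14 cases and rose in 2, with Cldn2 (-2.01 ± 0.14) and Cldn15 (-1.44 ± 0.14), and the same counts adjusted over the list alone (adjusted p = 0.0354 with an estimated correlation). Enteroendocrine markers fell in 4 of 8 cases, Neurog3, Pax4, Insm1 (-2.04 ± 0.19) and Gfra3 (at least 1.29-fold), with 5 adjusted over the list alone (adjusted p = 0.0354 with an estimated correlation). Of 17 bile acid and xenobiotic genes 10 fell, such as Nr1h3 (-1.42 ± 0.16) and Nr1i3 (-1.03 ± 0.17), and 11 adjusted over the list alone (adjusted p = 0.512 with an estimated correlation). Of 21 hypoxia genes 12 fell and 3 rose, with Ak4 at -1.63 ± 0.15, and 12 and 4 adjusted over the list alone (adjusted p = 0.512 with an estimated correlation). Wnt targets fell in 6 of 14 cases, such as Axin2 (-1.18 ± 0.11), with 6 adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). These 7 lists passed at the preset correlation.

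The other lists did not pass with butyrate. They held changed members, but 44.6% of all genes changed, 2187 of 9291 higher and 1959 lower. Changed members are therefore likely in any list. Histone deacetylase genes rose in 7 of 16 cases and fell in 3, with Hdac6 at 0.74 ± 0.22 and Sirt1 at -1.32 ± 0.15 (adjusted p = 0.816). Of 15 genes responsive to deacetylase inhibitors 6 rose and 2 fell, with Gadd45b at 1.57 ± 0.15 and Klf4 at -0.94 ± 0.21 (adjusted p = 0.0923). Of 11 genes of short-chain fatty acid handling 1 rose and 2 fell (adjusted p = 0.879). PPAR and fatty acid oxidation genes rose in 7 of 19 cases and fell in 2, with Pex11a at 0.97 ± 0.10 (adjusted p = 0.409). Lipogenesis genes rose in 5 of 17 and fell in 4, with Scd2 at -0.84 ± 0.14 and Elovl5 at 0.78 ± 0.11 (adjusted p = 0.909). Cholesterol genes rose in 4 of 18 and fell in 3 (adjusted p = 0.909), and chylomicron genes rose in 1 of 14 and fell in 5, with Apoa4 at -0.55 ± 0.14 (adjusted p = 0.409). Glycolysis genes rose in 3 of 19 and fell in 7, with the glucose transporter Slc2a2 at -2.00 ± 0.26 (adjusted p = 0.477), and gluconeogenesis genes rose in 3 of 7 and fell in 1 (adjusted p = 0.909).

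The counts that follow for butyrate are likewise to be read against 44.6% of all genes changed. Among immune and stress lists, NF-kB genes rose in 7 of 24 cases and fell in 3 (adjusted p = 0.876). Interferon genes rose in 3 of 19 and fell in 2, with Bst2 at 1.32 ± 0.35 (adjusted p = 0.909). Antimicrobial genes fell in 3 of 16 and AhR targets in 2 of 6 (adjusted p = 0.396 and 0.716). Oxidative stress genes rose in 2 of 18 and fell in 4, ER stress genes rose in 7 of 28 and fell in 8, with Xbp1 at -1.05 ± 0.08 (adjusted p = 0.777 and 0.409). Immediate early genes rose in 6 of 23 and fell in 6, with Egr1 at 1.66 ± 0.14 and Dusp4 at -1.58 ± 0.14, and heat shock genes rose in 4 of 13 and fell in 4 (adjusted p = 0.909 for both). Metal genes rose in 2 of 9 and fell in 2, and p53 targets rose in 7 of 17 and fell in 3, with Trp53inp1 at 1.26 ± 0.13 (adjusted p = 0.909 and 0.843). Enterocyte markers fell in 7 of 19 and rose in 1, goblet markers fell in 4 of 14 with Spdef at -2.55 ± 0.22, Paneth markers fell in 3 of 13 and tuft markers in 2 of 12 (adjusted p = 0.0813, 0.105, 0.134 and 0.477). Lists with too few genes to test were immune cells, where Cd14 (-1.85 ± 0.19), Laptm5 and Lcp1 fell among 4, endothelium, where Egfl7 rose (1.27 ± 0.24) and Esam fell (-1.68 ± 0.15) among 3, and mesenchyme, where 0 of 2 changed. All 5 follow-up genes changed: Hdac5 (0.75 ± 0.14), Hdac3 (0.60 ± 0.07) and Angptl4 (at least 1.01-fold) rose and Ffar2 (-1.51 ± 0.20) and Pparg (-0.86 ± 0.12) fell; they were chosen by the study on these samples.

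Propionate, on the slide of the control, raised Crip2 (2.44 ± 0.17), Ikbip (2.31 ± 0.18, another probe 0.68 ± 0.23), Aph1b (2.03 ± 0.18), Map3k12 (2.03 ± 0.19) and Clba1 (2.02 ± 0.20). It lowered Ihh (-2.73 ± 0.23), Neurog3 (-2.72 ± 0.23), Kmt5b (-2.43 ± 0.21, another probe -0.85 ± 0.19), Rep15 (-2.42 ± 0.23), Pax4 (-2.19 ± 0.19), Spdef (-2.09 ± 0.22) and the secretory cell factor Bhlha15 (-2.05 ± 0.16). It changed 2687 genes, 1446 higher and 1241 lower. Cell cycle genes fell in 15 of 29 cases and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.362 with an estimated correlation), with Ccnd1 at -0.99 ± 0.14. Enteroendocrine markers fell in 4 of 8 (4 adjusted over the list alone; adjusted p = 0.00231, and adjusted p = 0.0662 with an estimated correlation), with Insm1 at -1.56 ± 0.19. Stem cell markers fell in 6 of 13 and rose in 2, with Lgr5 at -1.42 ± 0.18 and Rnf43 at 0.80 ± 0.18 (9 and 2 adjusted over the list alone). Tight junction genes fell in 6 of 14 and rose in 2, with Cldn23 at -1.08 ± 0.12 (6 and 2 adjusted over the list alone). Stem and tight junction lists each had adjusted p = 0.0423, and adjusted p = 0.806 and 0.338 with an estimated correlation. The other 27 lists had adjusted p from 0.135 to 0.904. Of lists with too few genes to test, Cd14 (-0.95 ± 0.19), Laptm5 (-1.13 ± 0.23) and Lcp1 (-0.87 ± 0.20) fell among 4 immune genes, Esam (-1.06 ± 0.15) fell among 3 endothelial genes, and 0 of 2 mesenchymal genes changed. Of the follow-up genes Hdac5 (0.58 ± 0.14), Hdac3 (0.44 ± 0.07) and Angptl4 (at least 1.04-fold) rose and Ffar2 (-1.32 ± 0.20) and Pparg (-0.60 ± 0.12, another probe -0.40 ± 0.23) fell.

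Acetate changed 151 genes, 112 higher and 39 lower. Ikbip (1.13 ± 0.18), Fads3 (0.96 ± 0.11), Rem2 (0.94 ± 0.16) and Hap1 (0.89 ± 0.19) rose, and the retinoic acid receptor gene Rarg was at least 1.61-fold higher. Cc2d2a (-0.89 ± 0.19), Phtf1 (-0.86 ± 0.20), Epc2 (-0.84 ± 0.14) and Kmt5b (-0.83 ± 0.21) fell. Other detected probes gave 0.16 ± 0.23 for Ikbip, -0.05 ± 0.21 and 0.18 ± 0.22 for Hap1, 0.32 ± 0.28 for Rarg and -0.02 ± 0.19 for Kmt5b. Only the cell cycle list passed, lower, with 0 of 29 members changed over all genes or adjusted over the list alone (adjusted p = 0.00202, and adjusted p = 0.781 with an estimated correlation). Hdac3 differed by 0.26 ± 0.07 (adjusted p = 0.0665), Hdac5 by 0.20 ± 0.14, Pparg by -0.17 ± 0.12 and Ffar2 by -0.10 ± 0.20, and Angptl4 was below background in both groups. Acetate and control lay on different slides. The count was 11 with the array row as a covariate, 10 with only the groups compared, 73 without the detection filter, and 37 without acetate replicate 4.

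At the matched dose of 5 mM and time of 3 h the acids differed from each other in many genes. Chain length as such was not tested. Butyrate differed from propionate in 1113 genes (620 higher, 493 lower), such as Crip2 (1.31 ± 0.17), H1f2 (1.25 ± 0.15), Isx (-1.64 ± 0.14), Neurog3 (-1.61 ± 0.23) and Cdx2 (-1.40 ± 0.12), and 605 with the array row as a covariate or 710 without butyrate replicate 4. Tight junction genes were lower with butyrate than with propionate in 7 of 14 cases (7 adjusted over the list alone; adjusted p = 0.000107, and adjusted p = 0.0210 with an estimated correlation). Stem cell, cell cycle, bile acid and xenobiotic, Wnt, enteroendocrine and enterocyte lists also passed, lower, with 5 of 13, 3 of 29, 4 of 17, 4 of 14, 1 of 8 and 2 of 19 members lower (8, 3, 4, 4, 3 and 2 adjusted over the list alone). With an estimated correlation their adjusted p was 0.150, 0.563, 0.561, 0.150, 0.150 and 0.721. Propionate differed from acetate in 2111 genes (1126 higher, 985 lower), such as Neurog3 (-2.52 ± 0.23), Ihh (-2.45 ± 0.23) and Crip2 (2.13 ± 0.17). Genes responsive to deacetylase inhibitors passed as higher with propionate than with acetate (5 of 15 higher and 1 lower, 6 and 1 adjusted over the list alone). Cell cycle (9 of 29 lower, 12 adjusted over the list alone), tight junction (8 of 14 lower and 2 higher, 8 and 2), stem cell (5 of 13 lower, 5) and enteroendocrine lists (3 of 8 lower, 3) passed as lower. With an estimated correlation the adjusted p of these 5 lists was 0.560, 0.584, 0.242, 0.584 and 0.127. Between butyrate and acetate 8 lists passed, 1 higher and 7 lower, of which 2 passed with an estimated correlation, tight junctions (adjusted p = 0.0417) and enteroendocrine markers (adjusted p = 0.0421). For other genes the difference of butyrate and propionate did not pass. It was -0.19 for Ffar2 (95% interval -0.59 to 0.22), -0.03 for Angptl4 (-0.42 to 0.36), 0.17 for Hdac5 (-0.11 to 0.45), 0.16 for Hdac3 (0.01 to 0.31, adjusted p = 0.174) and -0.38 for Kmt5b (-0.80 to 0.04). Acetate and butyrate shared a slide; the other pairs did not.

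**Figure D3:**
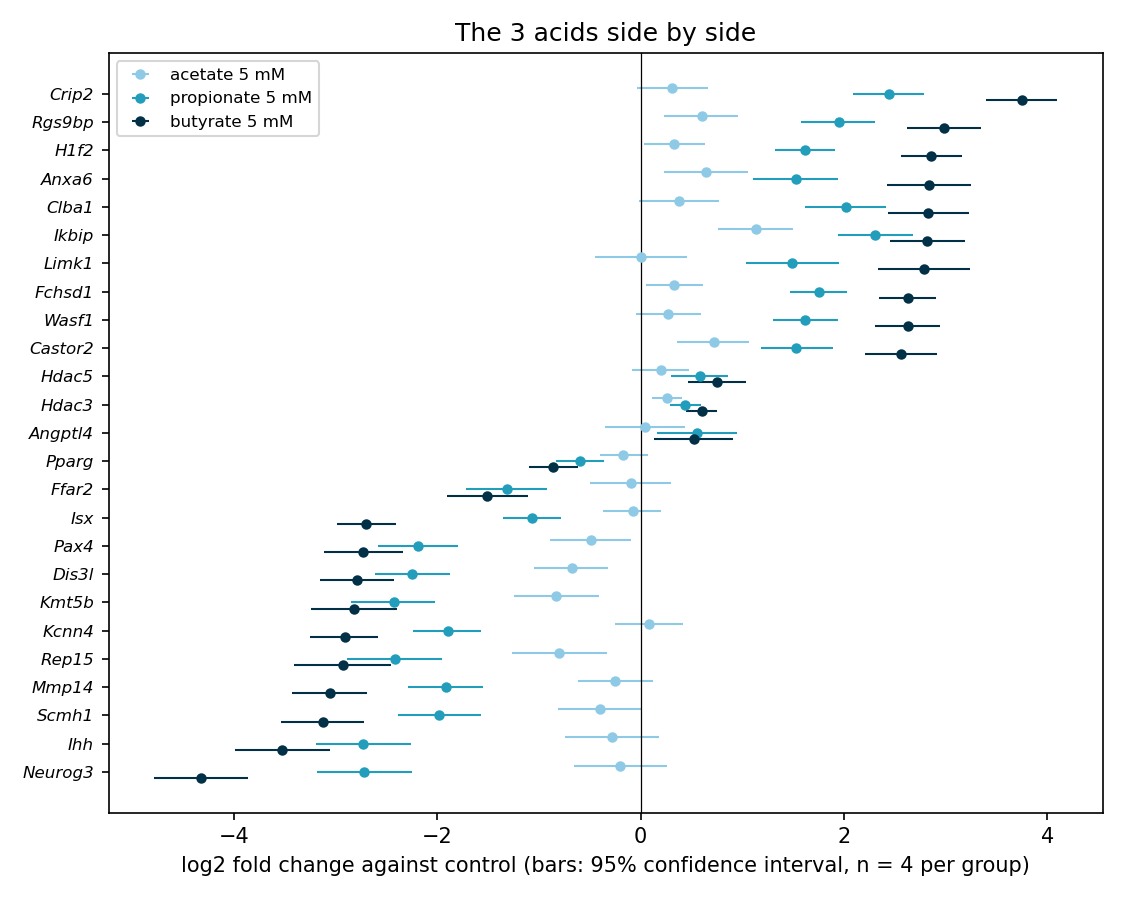
Points give the log2 fold change against control (x axis) of 25 genes (y axis) for 5 mM acetate, propionate and butyrate, and bars the 95% confidence interval with 4 arrays per group. Pax4 with butyrate and Angptl4 in control were not above background, and another probe of Castor2 gave -0.09 ± 0.24 with butyrate. Neurog3 stood at -0.20 with acetate, -2.72 with propionate and -4.33 with butyrate.

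The propionate and butyrate responses correlated across genes at r = 0.888. Since they share control arrays, unchanged groups would give 0.499. With the controls split r was 0.771, and the covariance was 0.218 against a simulated 0.0149. Both raised 1297 genes, where independent lists would share 340, and both lowered 1113, where they would share 262. With the controls split these were 907 against 219 and 732 against 161. Unchanged groups against shared controls shared at most 1 called gene in 100 simulations. No gene was changed in these, so that count is low by design. It cannot tell how far shared controls raise the overlap of changed genes. Acetate correlated with propionate at 0.518 and with butyrate at 0.491, or 0.294 and 0.319 with the controls split, with covariances of 0.0487 and 0.0659 against 0.0149. Acetate and propionate both raised 102 genes, against 17.4 for independent lists, and lowered 28, against 5.21. Acetate and butyrate both raised 100, against 26.4, and lowered 31, against 8.22. With the controls split, acetate shared 30.7 higher and 3.83 lower genes with propionate, against 4.45 and 0.873, and 33.2 and 5.00 with butyrate, against 7.49 and 1.56. These are means of 6 splits, and in both pairs the lowest split shared 8 higher and 0 lower genes.

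Whether a bacterial response resembled that to an acid was tested over 6 pairs, none of which share arrays. The A. muciniphila response correlated across genes with propionate at r = 0.674 (rho = 0.576), butyrate at 0.620 (0.523) and acetate at 0.442 (0.402), each with an exact p of 0.0286, the smallest possible, and 0.0571 adjusted over the 6. The F. prausnitzii response gave 0.279 (0.270) with butyrate, 0.185 (0.177) with propionate and 0.100 (0.113) with acetate, each with an exact p of 0.0857. Its reference medium itself contained propionate and acetate, and effects shared with the conditioned medium cancel in that response. With the array row as a covariate r was 0.451 with acetate and 0.387 with propionate. There the same row slope was removed from both responses, which by itself can raise r. No conclusion on resemblance is drawn from these values. Without F. prausnitzii medium replicate 1, r was 0.330 with butyrate, 0.225 with propionate and 0.117 with acetate, each with an exact p of 0.0286. The correlation with acetate also reached that p without acetate replicate 1 (0.0946) or control replicate 2 (0.113). Over the 2094 genes changed by A. muciniphila, the median change in the direction of that response was 0.16 with acetate, 0.46 with propionate and 0.58 with butyrate on the log2 scale. Per-array scores differed for each pair of acids (exact p = 0.0286).

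The bacterial media were set against control as background. They lay on other slides than the control, and slide and medium cannot be told apart. A. muciniphila medium had higher Hmox1 (3.60 ± 0.25) and Rsad2 (3.43 ± 0.50), and at least 12.6-fold higher Defa31, a Paneth cell defensin. Reg3b (-2.36 ± 0.33), Eef1a1 (-2.03 ± 0.20), Eci3 (-1.46 ± 0.26) and Pdzk1 (-1.41 ± 0.22) were lower. It differed in 1253 genes (683 higher, 570 lower), 798 with only the groups compared. Interferon genes were higher in 14 of 19 cases (17 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation), with a mean score of 1.07 ± 0.95 (SD, n = 4) and single arrays from 0.46 to 2.49. Oxidative stress genes were higher in 11 of 18 and lower in 1 (11 and 1 adjusted over the list alone; adjusted p = 2.29e-06 with an estimated correlation). ER stress genes were higher in 17 of 28 (20 adjusted over the list alone; adjusted p = 0.0203 with an estimated correlation) and immediate early genes in 12 of 23, with 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.00226 with an estimated correlation). Enterocyte markers were lower in 7 of 19 (11 adjusted over the list alone; adjusted p = 0.318 with an estimated correlation). Genes of PPAR targets and fatty acid oxidation were lower in 7 of 19 (9, and 1 higher, adjusted over the list alone), chylomicron genes lower in 6 of 14 (8), hypoxia genes higher in 5 of 21 (7), and cell cycle genes lower in 5 of 29 and higher in 1 (5 and 1). With an estimated correlation their adjusted p was 0.305, 0.318, 0.318 and 0.366.

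F. prausnitzii medium, which per the labels contained 9 mM propionate and 2.5 mM acetate before 85 µl was added to 500 µl, differed from control in 3348 genes (1768 higher, 1580 lower). Crip2 (2.82 ± 0.17), Clba1 (2.35 ± 0.20) and Fchsd1 (2.32 ± 0.14) were higher, and Ihh (-3.08 ± 0.23), Neurog3 (-3.08 ± 0.23), Eef1a1 (-2.85 ± 0.20) and Rep15 (-2.74 ± 0.23) were lower. Defa31 was at least 5.81-fold higher. Cell cycle genes were lower in 17 of 29 and higher in 1 (20 and 2 adjusted over the list alone; adjusted p = 0.485 with an estimated correlation). Enteroendocrine markers were lower in 5 of 8 (6 adjusted over the list alone; adjusted p = 0.0524 with an estimated correlation). Stem cell markers were lower in 6 of 13 and higher in 1 (7 and 1 adjusted over the list alone), bile acid and xenobiotic genes lower in 10 of 17 and higher in 1 (10 and 1), enterocyte markers lower in 8 of 19 (9), and chylomicron genes lower in 7 of 14 and higher in 1 (7 and 1). With an estimated correlation their adjusted p was 0.492, 0.655, 0.774 and 0.819. Untested for too few genes, 3 of 4 immune genes and 1 of 3 endothelial genes were lower, among them Laptm5 (-1.50 ± 0.23) and Esam (-1.40 ± 0.15). The response correlated with that to butyrate at r = 0.870 and to propionate at 0.858, where unchanged groups against shared controls give 0.499. With the controls split, so that no array is shared, r was 0.772 and 0.722. The covariances were 0.249 and 0.172 against a simulated 0.0149. It shared 1456 higher and 1278 lower genes with butyrate, against 416 and 333 for independent lists, and 1166 and 987 with propionate, against 275 and 211. With the controls split these were 1061 and 870 against 278 and 214, and 783 and 611 against 167 and 120.

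**Figure D4:**
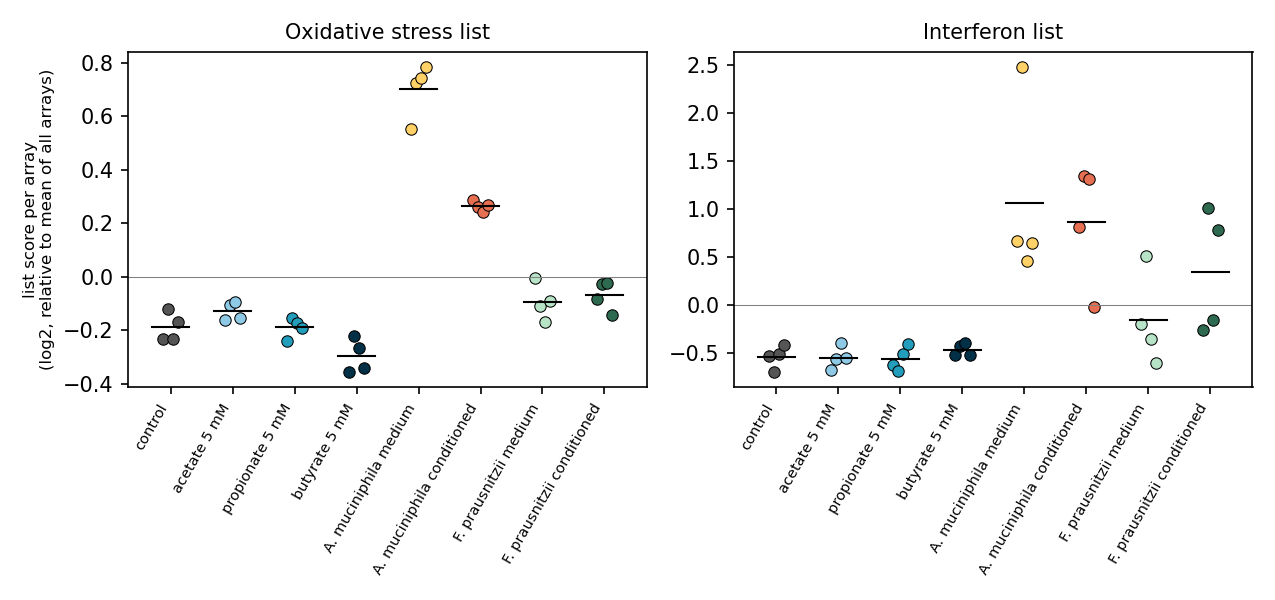
Each point is the mean log2 value of the tested members of a list on 1 array, relative to the mean of all 32 arrays (y axis), by group (x axis), and lines are means of 4 arrays. The oxidative stress score averaged 0.70 in A. muciniphila medium and 0.26 in its conditioned medium, and the interferon score reached 2.49 on 1 array of A. muciniphila medium.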

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

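The tests of the 2 patterns weighed here, and the count of splits for the difference of the bacterial responses in its final form, were chosen after the results were seen. Of 228 groups of 4 arrays examined for a value far from the rest, 10 stood out; chance alone gives about 1 in 20. Mean intensity was 487 on acetate replicate 1 against 578 to 586 on the others, and the first principal component was -22.0 on control replicate 1 against -26.9 to -26.8. On the log2 scale, Vps37d was 5.71 on A. muciniphila medium replicate 1 (others 4.97 to 5.05), Hdac5 10.01 on F. prausnitzii medium replicate 1 (9.75 to 9.77) and Pparg 9.06 on acetate replicate 1 (9.29 to 9.33). In control replicate 1, Rbm6 was 5.80 (6.40 to 6.52) and Aph1b 5.84 (5.05 to 5.18). Neurog3 was 7.73 on propionate replicate 1 (8.13 to 8.21) and 5.72 on butyrate replicate 4 (6.62 to 6.72), where Rgs9bp was 8.67 (8.15 to 8.19).

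The responses to both bacteria differed in 881 genes by a test of the difference itself. Added volumes were unequal, 250 µl for A. muciniphila and 85 µl for F. prausnitzii. The media differed too, with propionate and acetate in that for F. prausnitzii, and the test does not part volume or medium from bacterium. Of 100 drawn splits of the 16 arrays, a split and its mirror counted as one, 4 gave as many, the real one included, and the highest of the others gave 1591. When mirrors were counted apart 5 of 100 did, so this count lies at the edge of 0.05 and depends on that choice. All 4 kept the A. muciniphila arrays in their own groups, as 6 of the 100 splits did, and splits that mixed them gave at most 8 genes. The splits therefore speak for the A. muciniphila groups, and chance in the placing of the F. prausnitzii arrays is not excluded. In the other comparisons 1 of 35 splits, the real one, gave as many genes: 2094 for A. muciniphila (highest other 47), 151 for acetate (3), 2687 for propionate (204), 4146 for butyrate (1082), 3605 for butyrate against acetate (602), 1113 for butyrate against propionate (23), 2111 for propionate against acetate (19), 1253 for A. muciniphila medium (25) and 3348 for F. prausnitzii medium (416). For F. prausnitzii conditioned medium, with 0 genes, all 35 did and the highest other gave 9.

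The A. muciniphila response resembled those to propionate and butyrate. Position on the slide as the common cause is argued against by butyrate minus acetate, whose rows run the other way, since its correlation with the A. muciniphila response was 0.513 and not below 0. Propionate as the active product, rather than another acid, stays open: the correlation with propionate was higher than with butyrate by only 0.0541, and the acid responses resemble each other. No fraction of the supernatant was analysed here.

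The response to F. prausnitzii medium without growth also correlated with those to propionate and butyrate. Shared controls are argued against, since F. prausnitzii medium minus A. muciniphila medium correlated with butyrate minus acetate, which shares no array with it, at r = 0.668 (exact p = 0.0286, the smallest possible; highest other split 0.639). A difference between all bacterial-medium arrays and the others is argued against by A. muciniphila medium, which correlated with butyrate at 0.0455 with the controls split. Propionate in the medium may be a source and cannot be told apart from other components or from slide 3: after mixing it stood at 1.31 mM against 5 mM, yet over genes changed between butyrate and acetate the score exceeded that of propionate by 0.0310 (exact p = 0.286). Acetate alone is argued against: after mixing it stood at 0.363 mM, yet over genes changed by propionate the medium's score of 0.561 exceeded that of 5 mM acetate by 0.410 (exact p = 0.0286, the smallest possible).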

How the results depend on the processing

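All alternatives reported here but 2 were planned before the data were examined. A. muciniphila medium in place of control as the reference for F. prausnitzii medium was chosen after seeing the data and gave 3384 genes against 3348. The 11 counts stayed within 1.5 times with the authors' deposited values, no background correction, cyclic loess, the stricter filter, array weights and all probes. The setting with all probes took each gene's probe of smallest p. It therefore favours calls and cannot test the choice of probe. The array row as a covariate gave 1156 genes for A. muciniphila, 11 for acetate and 605 for butyrate against propionate; row and group overlap, and the cause was not tested. With only the groups compared, fewer arrays estimate the spread, and acetate gave 10 and A. muciniphila medium 798. Without the detection filter more genes are tested, and acetate gave 73. Leaving out 1 array gave 37 (without acetate replicate 4) to 188 genes for acetate, with 68 without acetate replicate 2 and 63, 39 and 51 without control replicates 2, 3 and 4. It gave 710 (without butyrate replicate 4) to 1074 for butyrate against propionate and 0 to 19 for F. prausnitzii, the 19 without its medium replicate 1. That array and A. muciniphila medium replicate 2, without which that medium gave 878 genes, were singled out after seeing the data. Correlation of A. muciniphila with acetate over genes changed by acetate was 0.804 (exact p = 0.0571). With the array row in both responses F. prausnitzii gave 0.451 with acetate and 0.387 with propionate. There the same row slope was removed from both responses, which by itself can raise r, so no conclusion is drawn from these values. Leaving out 1 array gave 0.0738 to 0.117 with acetate, 0.145 to 0.225 with propionate and 0.225 to 0.330 with butyrate, the highest without F. prausnitzii medium replicate 1. Exact p was 0.0286 without that array for all 3 acids, and for acetate also without acetate replicate 1 (0.0946) or control replicate 2 (0.113); the cause was not tested. Of 155 gene list results in the main comparisons, 15 lost their call with an estimated correlation, 5 lost and 15 gained one with the array row, 2 lost and 16 gained one with fry, and 6 gained one without the detection filter. Of 421 results of named genes, 94 lost their call with the array row, 34 without the detection filter, 31 with only the groups compared, and at most 9 in any other refit of all arrays; leaving out 1 array lost 296 calls and gained 4 over all such fits. No result reversed. The labels give no replicate numbers, so samples were not treated as pairs. Exact p-values and splits take no account of array position. Deviations from group means correlated between same-position arrays at 0.111 to 0.272 for propionate against control and 0.0688 to 0.153 for F. prausnitzii. In the other comparisons the lowest such r lay between -0.110 and 0.0202 and the highest between 0.0505 and 0.333. Of the 4 arrays of the first group, 4 matched best with their own position for propionate and for F. prausnitzii. This held for 3 with A. muciniphila and for 1 or 2 in each of the others. The array on row 2 or 6 had the highest second principal component in 8 of 8 groups. Array position within each 4 rows was therefore added as a factor, after seeing the data; it moved no count by over 1.5 times, except that F. prausnitzii gave 1 gene (P2ry6, -0.84, adjusted p = 0.0322). With it 2 gene list results and 1 named gene gained a call and none lost one. The factor assumes the same position effect on every slide, so it does not test a pairing of arrays within a slide. Signal over background limits genes near background, such as Angptl4.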

Other observations

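The genes and the histone group in this part were chosen after the values were seen, and so were its tests except the one that parted the A. muciniphila medium arrays. All 16 arrays of the bacterial media lay above all 16 arrays of the acids and control for 5 genes and below for 6. Defa31 stood at 4.91 ± 0.24 (SD, n = 4, log2) in control and 4.63 ± 0.10 in butyrate, not above background in either, and at 8.86 ± 0.50 in A. muciniphila medium and 8.13 ± 0.64 in F. prausnitzii conditioned medium. Reg3b stood at 11.47 ± 0.89 in control and 9.11 ± 0.34 in A. muciniphila medium. Interferon genes varied between arrays of one group: Usp18 was 8.09 ± 1.34 in A. muciniphila medium, 6.46 ± 1.60 in F. prausnitzii conditioned medium, and its probe was not above background in control. The interferon score was highest on row 2 or 6 in every bacterial-medium group, and in none of the acid and control groups. There it was 2.49 in A. muciniphila medium, 1.35 in its conditioned medium, 0.52 in F. prausnitzii medium and 1.02 in its conditioned medium. Medium, slide and culture cannot be told apart for these genes, nor can array position for the spread of interferon genes.

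Histone genes, taken by name, numbered 53. With butyrate 15 rose and 3 fell, with propionate 10 rose and 2 fell, and with acetate 0 changed. Between propionate and acetate 17 were higher and 1 lower, between butyrate and acetate 17 and 3, between A. muciniphila medium and control 17 and 0, and between F. prausnitzii medium and control 6 and 11. As a group, with adjusted p over the 11 comparisons, they passed as higher in the first 3 of these 4 (adjusted p = 0.000213, 0.00945 and 0.000213) and as lower with acetate against control (0.0177), but not with propionate (0.0620), butyrate (0.159) or F. prausnitzii medium (0.368) against control, and in none of the others. With an estimated correlation none of the 11 passed, the lowest at 0.283.

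Oxidative stress genes were higher in A. muciniphila medium than in both control and conditioned medium. Chance values of the shared medium arrays are argued against: with the medium arrays parted 2 and 2 in 6 ways, the lowest median difference of one pair from control was 0.458, and the median of the other pair lay above conditioned medium in all 6. Against conditioned medium, both groups lay on 1 slide, so a whole-slide difference cannot enter, and array position is argued against by the F. prausnitzii pair on the same rows of another slide, at -0.0244 (exact p = 0.543). Against control the slide stays open, since conditioned medium on that slide also lay above control by 0.453 of the 0.889 seen for medium.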
